A study of Homo sapiens with 14 samples.

How the data were processed

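RNA of 14 cultures of HEK293, a human embryonic kidney cell line, was hybridised to 14 Affymetrix arrays, per the labels. Cells had been transfected with a HOXD9 vector carrying an HA tag or a HOXD13 vector carrying a V5 tag, or with a vector of the same tag, and were selected with G418, a drug that kills cells without the resistance gene of the plasmid. Per the labels there were 3 arrays of the HA vector, 3 of the V5 vector, and 4 for each HOX gene: a mixed population and clones a, b and c, which were picked from that population. The 4 lines of a HOX gene are therefore not fully independent of each other. The labels call the vector arrays biological replicates and do not say how their cultures were separated, so p-values measure the spread between these samples, part of which may be technical.

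The deposited values are GCRMA expression values on the log2 scale, 1 per probe set, with the method credited to the submitters' processing notes and the scale read from the values, which run from 1.83 to 15.5. GCRMA corrects the background by probe sequence, puts arrays on 1 distribution and summarises the probes of a set. The version of the software and the genome build are not given in the sources used here, and no coordinates are printed. The sorted values of the 7 arrays of the HA tag set (HA vector and HOXD9) were identical to within 0.00102, and those of the 7 arrays of the V5 tag set to within 0.00195, while the 75th percentile was 6.27 in the HA set and 7.02 in the V5 set. The 2 sets were thus normalized separately, and levels were compared only within a set. GCRMA leaves transcripts that are not detected near a common floor at a log2 value of about 2, where a fold change depends on the background model. The arrays carry no depth, and their number limits the precision.

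The deposited values cover 54675 probe sets, of which 62 are array controls. In the platform annotation of 2016, 41097 probe sets had 1 gene symbol, 1801 had several and 11777 had none listed. Symbols were updated through the RefSeq genes of GRCh38.p14, which matched 41043 of the probe sets with 1 gene. A probe set was tested when its value was at least 5 on at least 3 of the 14 arrays, which left 19816. Each gene was represented by its probe set with the highest mean over the 14 arrays, and probe sets of several genes or of none were left out, so 10349 genes were tested. By this rule HOXD9 and HOXD13 were read as genes by the dimmer HOXD9 and the middle HOXD13 probe set, and all probe sets of both were examined separately.

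A model of 4 group means over all 14 arrays was fitted to the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 10 residual degrees of freedom and a prior of 3.02, so that the groups share 1 estimate of the spread. Tests were two-sided, adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Contrasts were HOXD9 minus HA vector, HOXD13 minus V5 vector, and the difference of these effects. Adjusted p-values below are from limma unless another test is named. Gene lists were tested with limma's camera at a preset correlation between genes of 0.01, adjusted over the 33 lists with at least 3 measured members in each contrast, and again with an estimated correlation. The 37 lists (HOX clusters, pathways, cell cycle, stress responses and markers of other cell types) were fixed before the data were examined, as were the contrasts, the filter and the other settings tried, apart from those named below as added later; 694 of their 698 entries matched a symbol. Values were read with the R package data.table, version 1.17.8, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

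Genes to be named were chosen by a rule fixed before the data were examined. It took the transgene, the 8 largest rises and 8 largest falls among called genes with an absolute log2 fold change of at least 1 and all 4 HOX arrays beyond the 3 vector arrays, the 2 called members with the largest change in each list with at least 2 called members, and the 5 largest differences of effect in each direction. RAC3, ARC, the genes ranked after RAC3 in the HOXD9 comparison, and the other list members named were chosen after their values were seen.

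The code was tested on simulated data made from the real means, with 200 of the 10349 genes changed. When every group was given its own real spread, the HOXD9 contrast recovered 76.1% of the 67 genes changed by a log2 value of 1 and 97.0% of the 66 changed by 2, and the HOXD13 contrast recovered 65.7% and 95.5% of the same numbers of genes. In that simulation 18.9% of the HOXD9 calls and 13.8% of the HOXD13 calls were of unchanged genes, against the 5% that the threshold aims at. With equal spread in all groups these shares were 3.65% and 4.26%. The vector arrays differ far less among themselves than the HOX lines, with a median SD per gene of 0.05 for both vectors, 0.27 for HOXD9 and 0.26 for HOXD13. How this leads to false calls was not tested. A model with a spread for each group was tried as a remedy after this was seen and gave 28.2% and 30.8%, so it was kept as an alternative only. The share of genes with all lines on 1 side of their vectors was set against 20 simulations without change, in which each group had its real spread and the lines were independent.

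The 3 prime to 5 prime signal difference of the array's ACTB and GAPDH control probe sets was taken as a measure of RNA integrity. Alternatives were other filters on dim probe sets, quantile normalization of all arrays together, centring, an intensity trend with a robust prior, array weights, the mean of a gene's probe sets, all probe sets, a minimum fold change, fits on 2 groups only, a replicate block, an estimated correlation for gene lists and leaving out each array. Added after seeing the data were a model with the ACTB difference as a covariate, a fit without the 3 arrays of deviating ACTB difference, array weights estimated gene by gene, the spread for each group, the HOXD cluster list without the transfected gene, and the difference of effects for the splits of each set with the most calls. A comparison of the HA with the V5 vector, and fits that pool both vectors, were intended before the data were examined and were not run, since these arrays were normalized separately: 97.9% of genes were lower on all 3 HA than on all 3 V5 vector arrays. Whether same-numbered vector arrays or same-named lines are paired was checked and is described with the replicate block. The part of the HOXD9 and HOXD13 transcripts that each probe set reads is not given in the sources used here, so a probe set outside the transfected sequence would not measure the transgene.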

Results

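Expression was measured on 14 arrays of HEK293 cells, a human embryonic kidney line, stably transfected with HOXD9 or HOXD13 or with a vector of the same tag. HOXD9 and HOXD13 are homeodomain transcription factors of the HOXD cluster that pattern the limbs and the urogenital tract. The HOXD9 group held 4 lines (a mixed population and clones a, b and c) beside 3 HA vector arrays. The HOXD13 group held 4 lines of the same kind beside 3 V5 vector arrays. The series title places the HOXD region in a study of tumour formation by carbon nanotubes, and the arrays ask what each factor does to the transcripts of a cell line. The lines of a HOX gene varied more than the vector arrays. The median SD per gene was 0.05 (log2, n = 3) in both vector groups, 0.27 (n = 4) in the HOXD9 lines and 0.26 (n = 4) in the HOXD13 lines.

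Both transgenes were detected in every line that carried their name; adjusted p-values of their probe sets are over all probe sets tested. The brighter HOXD9 probe set of these lines stood at 6.99 ± 0.52 (log2, SD, n = 4) in the HOXD9 lines and at 2.73 ± 0.18 (n = 3) in the HA vectors. This rise of 4.26 (SE 0.21, adjusted p = 7.42e-07) is 19.2-fold, but the vectors lie near the floor of the array and the fold depends on the background model. The dimmer HOXD9 probe set read 4.40 ± 0.09 against 4.22 ± 0.02 and did not pass (log2 fold change 0.19, adjusted p = 0.653). The brightest HOXD13 probe set of the HOXD13 lines rose from 6.93 ± 0.09 (n = 3) to 12.43 ± 0.17 (n = 4), by 5.50 (SE 0.13, 45.2-fold, adjusted p = 2.23e-11). The dimmest HOXD13 probe set of these lines rose by 5.05 (SE 0.11, 33.1-fold, adjusted p = 1.45e-11) from 3.31 ± 0.22 in the V5 vectors. That level is near the floor, so this fold too depends on the background model. The middle HOXD13 probe set was already high in the V5 vectors at 8.94 ± 0.01 and rose by 0.98 (SE 0.28, adjusted p = 0.0473), with clone c at 8.87. That call ended without any 1 array other than HOXD9 clone c or HOXD13 clone c (adjusted p up to 0.146). In the HOXD9 lines no HOXD13 probe set passed, the nearest being the brightest with a log2 fold change of 0.40 (adjusted p = 0.178).

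**Figure D1:**
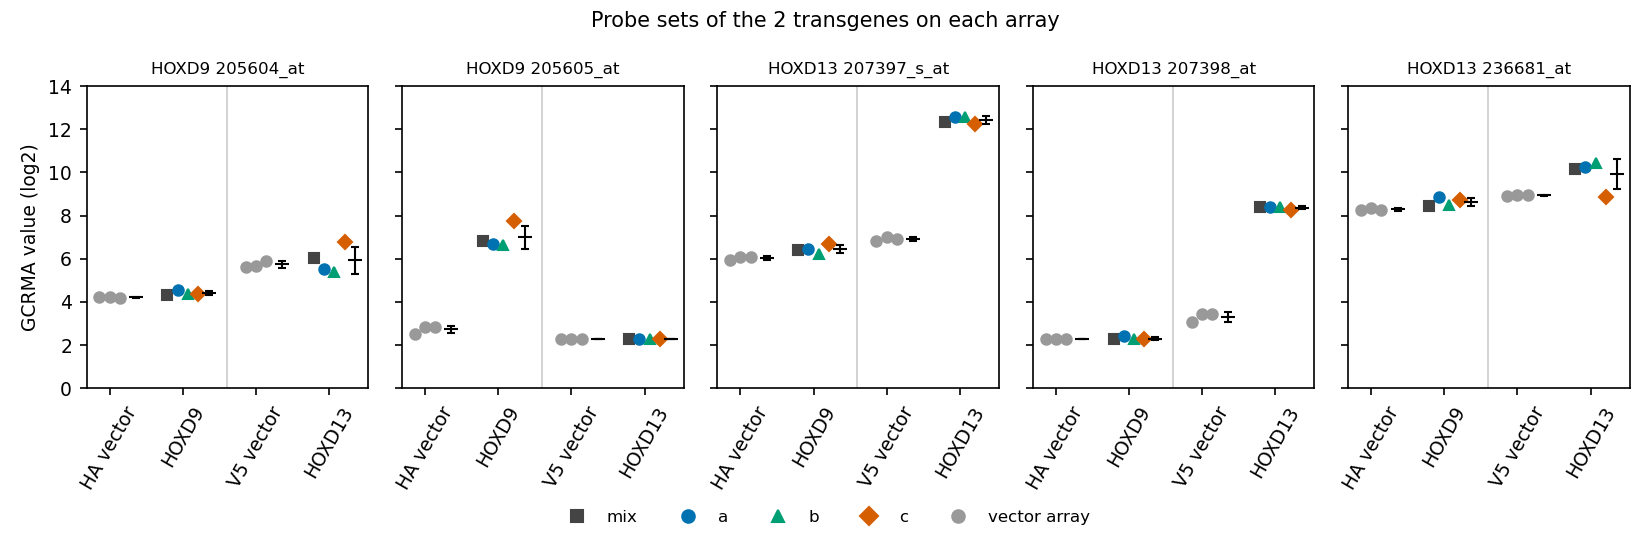
Each panel plots 1 probe set of HOXD9 or HOXD13 on the log2 scale for the 14 arrays, with symbols for the mix and clones a, b and c, grey circles for vector arrays, black bars for the group mean and SD, and a grey line between the sets normalized separately. The brighter HOXD9 probe set lies between 6.65 and 7.76 in the HOXD9 lines against at most 2.83 in the HA vectors, and the brightest HOXD13 probe set lies between 12.24 and 12.59 in the HOXD13 lines against at most 7.01 in the V5 vectors.

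HOXD9 expression went with 1 called gene. RAC3, which encodes a small GTPase that acts on the actin cytoskeleton, rose by 0.99 (SE 0.11, 1.99-fold, adjusted p = 0.00615) from 8.10 ± 0.07 (n = 3) in the HA vectors. Its shift was 1.03 in the mix and 0.99, 0.80 and 1.14 in clones a, b and c. The next genes by p-value moved the same way in all 4 lines and missed the threshold. They were NPM3, a nucleolar histone chaperone (log2 fold change 0.95), and the zinc finger genes ZNF595 (0.55) and ZBTB48 (0.59), each at an adjusted p of 0.0837. BCL11A, a repressor of fetal globin genes, followed with -0.51 (adjusted p = 0.0958). Among genes, each read by 1 probe set, none was called with an at least 2-fold change by limma, HOXD9 itself being read by its dimmer probe set there, while 2429 of 10349 genes had an unadjusted p under 0.05.

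No gene group was called in the HOXD9 lines. By camera 0 of 33 lists passed, with 2 at an unadjusted p under 0.05 and a smallest adjusted p of 0.629. With an estimated correlation 0 had an unadjusted p under 0.05. Of the 7 measured members of the HOXD cluster 0 were called, with a median log2 fold change of 0.19. They include HOXD9 on its dimmer probe set, and without it the median was 0.17. The 8 measured interferon-stimulated genes had the largest median, 0.40, with 0 called. The 25 nuclear genes of oxidative phosphorylation had a median of 0.12 with 0 called. RAS-MAPK output genes, which growth factor signalling induces, had a median of 0.22 over 17 genes, 0 of them called.

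The HOXD9 lines differed from each other and shared a trend with gene length. Genes over 1 log2 unit from the vector mean numbered 5 in the mix, 619 in clone a, 23 in clone b and 1439 in clone c. The Spearman correlation of shift with genomic length in GRCh38.p14 was -0.365 in the mix and -0.243, -0.316 and -0.341 in clones a, b and c, against -0.0441, 0.0445 and -0.0128 in the HA vectors, over genes, which are not independent. In 3784 genes (36.6%) all 4 lines lay on 1 side of the HA vectors, against 8.02% in simulated data without change, with the real spread of each group and independent lines. Lines picked from 1 population are not independent, so the share without change is not known. The count of calls was 880 without clone b and 1100 without HOXD13 clone c, whose spread all groups share in the model. It was 0 without HA vector 1 or HA vector 3 (RAC3 adjusted p = 0.0854 and 0.0993). It was 50 with the ACTB 3 prime to 5 prime difference as a covariate and 102 without the 3 arrays of deviating ACTB difference. Simulated data with 200 changed genes and independent genes and lines gave 18.9% false calls, a share that cannot be carried over to 1 call.

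HOXD13 expression went with 1101 called genes, 298 higher and 803 lower than in the V5 vectors, of which 83 rose and 89 fell at least 2-fold. The largest rise was that of OR51E2, an olfactory receptor also found in prostate, from the floor of the array (2.07, n = 3) to 6.58 ± 0.31 (n = 4). Measured from that floor, its log2 fold change was 4.51 (SE 0.13, adjusted p = 5.15e-10). AMBN, an enamel matrix protein, rose by 3.06 (SE 0.35, adjusted p = 0.000550), and TOX3, a chromatin protein of the HMG box family, by 2.80 (SE 0.24, adjusted p = 5.69e-05). PTGER4, a receptor for prostaglandin E2, rose by 2.56 (SE 0.17, adjusted p = 3.64e-06), and RFX6, a transcription factor of pancreatic islet development, by 2.38 (SE 0.15, adjusted p = 3.34e-06). OR51E2 started at the floor, and AMBN, RFX6 and HSF2BP near it, at 3.23, 3.24 and 2.85, so their folds depend on the background model. FOS, an immediate early gene of the AP-1 complex, rose by 2.58 (SE 0.61, adjusted p = 0.0192) from 4.05, a dim level under the filter value of 5. HSF2BP, a protein of meiotic recombination, rose by 2.23 (adjusted p = 0.00952), and the antisense transcript PHEX-AS1 by 2.43 (adjusted p = 0.00408). TOX3 and PHEX-AS1 started at dim levels too, 4.15 and 4.24.

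The largest falls were smaller than the leading rises, several of which started at or near the floor. A fall cannot pass below the floor, so these sizes are not directly comparable. KLHDC7B and LINC02709 ended at 4.47 and 4.26, dim levels under the filter value of 5. DNAH17, an axonemal dynein heavy chain, fell by 2.16 (SE 0.32, adjusted p = 0.00186), or fell by 1.24 with the mean of its probe sets. KLHDC7B, a kelch domain protein, fell by 1.89 (SE 0.12, adjusted p = 3.34e-06). C1RL, a serine protease related to complement C1r, fell by 1.75 (SE 0.43, adjusted p = 0.0222). GSTZ1, an enzyme of tyrosine breakdown, fell by 1.64 (SE 0.28, adjusted p = 0.00427). The other 4 were noncoding transcripts: UNC5B-AS1 fell by 2.16, ATP6V0E2-AS1 fell by 2.07, SBF2-AS1 fell by 1.69 and LINC02709 fell by 1.67.

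Clone c moved least in 14 of these 16 genes, the exceptions being TOX3 and RFX6. Its shift in FOS was 0.23, against 2.82 in the mix and 3.32 and 3.95 in clones a and b. Its shift in C1RL was -0.38, against -2.57 in clone a. OR51E2, PTGER4 and RFX6 were higher in clone c too, by 4.27, 2.22 and 2.55. The naming rule required all 4 lines beyond the vectors, so the direction in clone c was fixed for these 16 genes and only its size was free. ARC, an activity-regulated immediate early gene outside the naming rule, rose by 3.37 (SE 0.88, adjusted p = 0.0297), although not every line lay beyond the vectors.

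**Figure D2:**
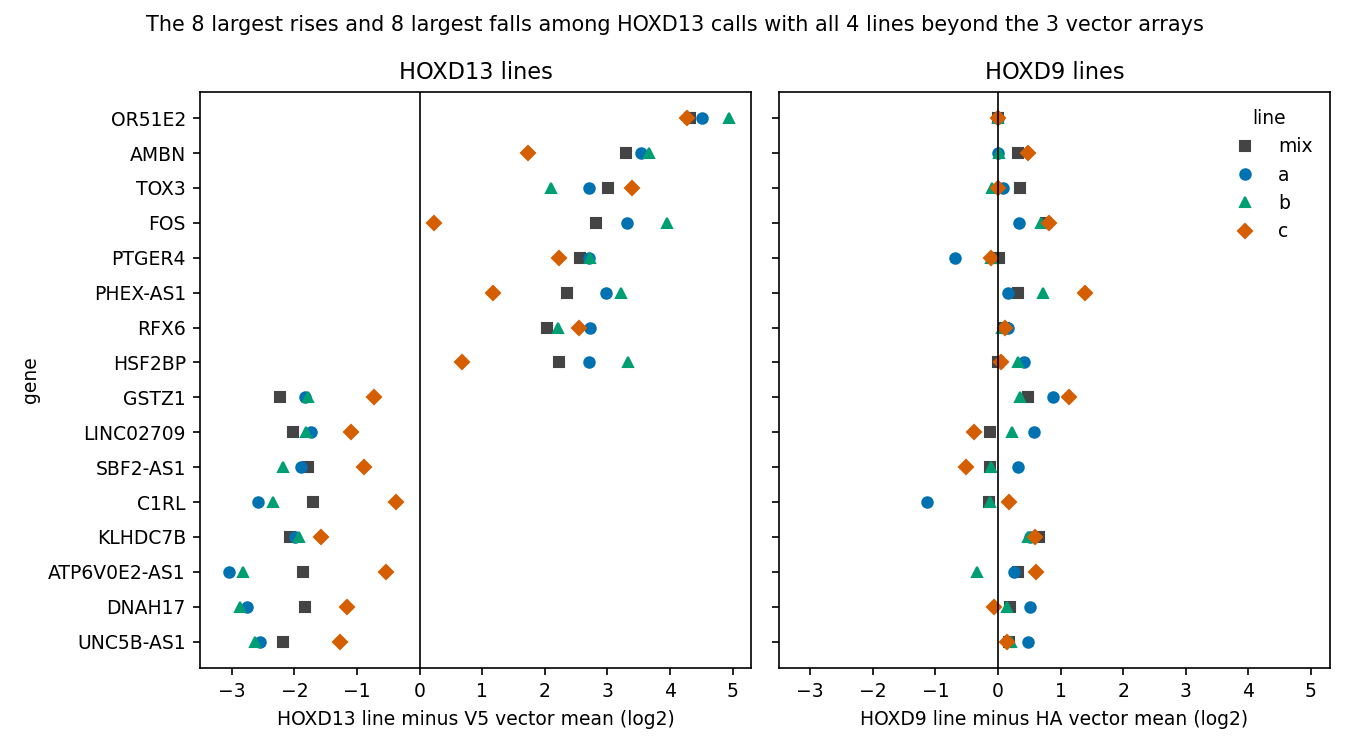
Each row is a gene and each symbol a line, placed at its log2 distance from the mean of the vector arrays of its own tag, for the HOXD13 lines on the left and the HOXD9 lines on the right. OR51E2 lies between 4.27 and 4.94 in the HOXD13 lines, whereas FOS lies at 0.23 in clone c and between 2.82 and 3.95 in the other lines.

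A few HOX genes and genes of limb and urogenital development were called higher with HOXD13, and most measured members of these lists did not pass. In the HOXD cluster 2 of 7 measured genes rose and 5 did not pass (4 adjusted over the list alone). HOXD10 rose by 0.45 (SE 0.12, adjusted p = 0.0351), and the other was HOXD13 on its middle probe set, which did not rise in clone c although the brightest and dimmest did. The list had a median of 0.45 (camera adjusted p = 0.0229; adjusted p = 0.433 with an estimated correlation). Without HOXD13, the transfected gene, the median of the other 6 was 0.38 and the list did not pass (camera adjusted p = 0.0539; adjusted p = 0.535 with an estimated correlation). In the HOXC cluster 1 of 6 rose (2 adjusted over the list alone), HOXC9 by 1.42 (SE 0.20, adjusted p = 0.00162). The median of that list was 0.31 (camera adjusted p = 0.0305; adjusted p = 0.535 with an estimated correlation). The HOXB cluster had 0 of 8 called and a median of -0.09 (camera adjusted p = 0.925), and no HOXA gene passed the filter. Of 20 genes of limb and urogenital development 3 rose and 17 did not pass (7 adjusted over the list alone, 5 of them higher). MSX2, a homeobox repressor, rose by 1.02 (adjusted p = 0.0400), BMP2, a bone morphogenetic protein, by 0.81 (adjusted p = 0.0119), and the ephrin EFNB2 by 0.65 (adjusted p = 0.0377). The list as a whole did not pass (camera adjusted p = 0.0626). The homeobox cofactor PKNOX2 fell by 0.84 (adjusted p = 0.0397), the only call among 9 measured HOX cofactors (2 adjusted over the list alone; camera adjusted p = 0.925).

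Of the targets of growth factor and morphogen signalling 4 lists passed upwards at the preset correlation and 0 with an estimated one (smallest adjusted p = 0.433 over all lists). Most members of each list were not called, where over all genes 298 of 10349 were called higher. The list medians were above 0 in the mix and in clones a and b and below 0 in clone c. Of 17 RAS-MAPK output genes 3 rose, 0 fell and 14 did not pass (10 adjusted over the list alone, all higher). Beside FOS, these were MYC, a transcription factor that drives growth, by 1.65 (SE 0.47, adjusted p = 0.0397), and DUSP6, a phosphatase that shuts off ERK, by 1.0 (SE 0.26, adjusted p = 0.0270). The list median was 0.66 (camera adjusted p = 9.85e-05; adjusted p = 0.535 with an estimated correlation). By line it was 0.63 in the mix, 0.98 in clone a, 1.12 in clone b and -0.22 in clone c. EGR1 (1.23, adjusted p = 0.0579), IER3 (1.37, adjusted p = 0.0994) and CCND1 (1.15, adjusted p = 0.0705) did not pass over all genes.

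Of 8 NOTCH targets 2 rose (5 adjusted over the list alone), the ligand JAG1 by 0.96 (SE 0.20, adjusted p = 0.01) and the repressor HEY1 by 0.75 (SE 0.20, adjusted p = 0.0340). The list median was 0.55 (camera adjusted p = 0.00129; adjusted p = 0.535 with an estimated correlation). Of 12 TGF-beta and BMP targets 1 rose and 1 fell (7 higher and 1 lower adjusted over the list alone). The pseudoreceptor BAMBI rose by 1.02 (adjusted p = 0.0492) and the inhibin subunit INHBE fell by 0.84 (adjusted p = 0.00888). The median was 0.56 (camera adjusted p = 0.00613; adjusted p = 0.535 with an estimated correlation).

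Of 9 WNT targets 3 rose and 1 fell (5 adjusted over the list alone, 4 of them higher). TNFRSF19, a receptor of the TNF family, rose by 1.12 (SE 0.15, adjusted p = 0.00144), the transcription factor SP8 by 0.86 and the stem cell receptor LGR5 by 0.44. APCDD1, an inhibitor of WNT signalling, fell by 0.87 (adjusted p = 0.0242). The median was 0.13 (camera adjusted p = 0.0305; adjusted p = 0.535 with an estimated correlation), and the list did not pass without clone b (adjusted p = 0.0724) or clone c (adjusted p = 0.0590). Of 18 growth factors and receptors 2 rose and 1 fell (6 adjusted over the list alone; camera adjusted p = 0.341). The EGF receptor ligand HBEGF rose by 1.37 (adjusted p = 0.0205), FGFR3 rose by 1.06 (adjusted p = 0.00805) and PDGFA fell by 0.88 (adjusted p = 0.00491).

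Histone genes had the largest median of the called lists, 1.15 over 7 measured genes (camera adjusted p = 0.0157; adjusted p = 0.535 with an estimated correlation). H2AC6 rose by 1.71 (SE 0.41, adjusted p = 0.0193), H2BC5 rose by 1.55 (SE 0.41, adjusted p = 0.0304), and 5 did not pass (4 rose adjusted over the list alone). The variant histones H2AX and H2AZ1 had values of 0.05 and -0.10. Nuclear genes of oxidative phosphorylation were the 1 list called lower, with 3 falls and 0 rises among 25 (6 falls adjusted over the list alone). UQCRC1 of complex III fell by 0.46 (adjusted p = 0.0298) and NDUFS1 of complex I fell by 0.42 (adjusted p = 0.0137). The median was -0.17 (camera adjusted p = 0.0305; adjusted p = 0.535 with an estimated correlation), and it lay between -0.11 and -0.22 in the 4 lines.

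**Figure D3:**
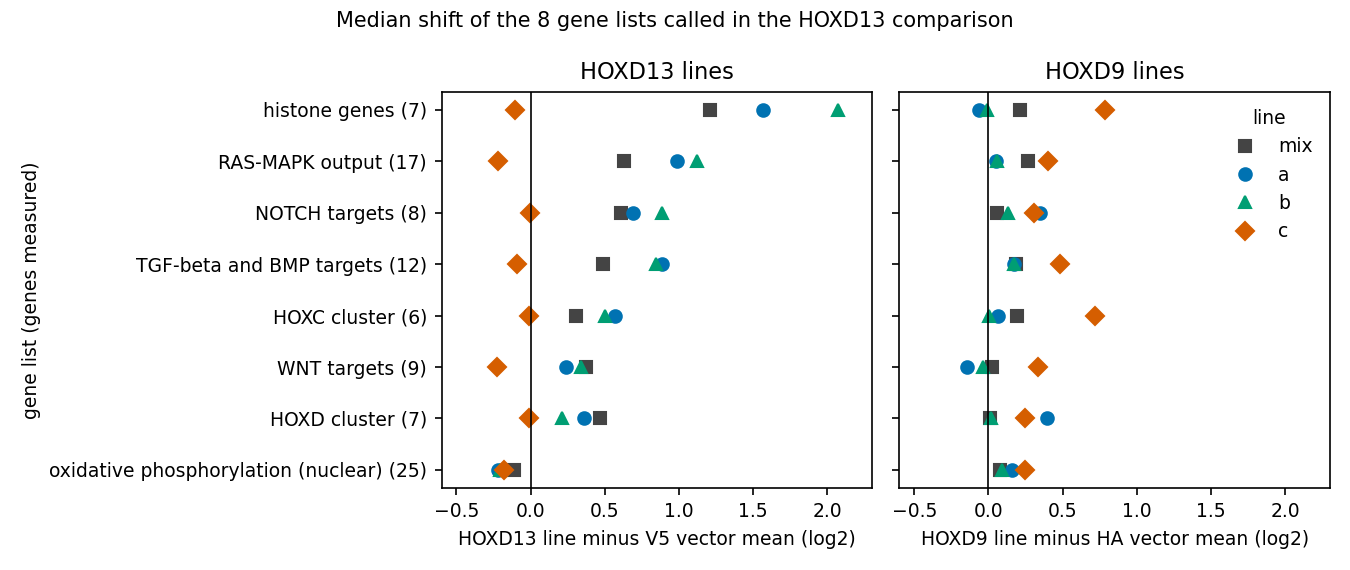
For each of the 8 lists called in the HOXD13 comparison, symbols give the median over the list of the log2 distance of a line from the mean of its vector arrays, with HOXD13 lines on the left, HOXD9 lines on the right and the number of genes measured in brackets. HOXD13 clone c lies below 0 in all 8 lists, and at -0.22 for RAS-MAPK output where clone b lies at 1.12.

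Genes of proliferation and cell death went both ways in the HOXD13 lines. Their calls were few, near the share over all genes (1101 of 10349 called). Of 21 S phase genes FEN1, a flap endonuclease, rose by 0.68 (adjusted p = 0.05; 0.0501 with each array centred) and CDC45, a replication helicase cofactor, fell by 0.74 (adjusted p = 0.00593), with 1 call adjusted over the list alone. Of 23 G2 and mitosis genes cyclin B2 (CCNB2) fell by 0.48 (adjusted p = 0.0159). The proliferation marker MKI67 was called higher by 1.29 on its brightest probe set, but 2 of its 4 probe sets were called lower and their mean was -0.50, so its direction is uncertain. The cell cycle inhibitor CDKN2B rose by 1.23 (SE 0.20, adjusted p = 0.00361), 1 of 2 calls beside MYC among 16 cyclins and inhibitors. Of 18 p53 targets 2 fell (2 adjusted over the list alone). BAX, an effector of apoptosis, fell by 0.83 (SE 0.12, adjusted p = 0.00161), and the stress protein SESN1 fell by 0.72 (adjusted p = 0.0260). BCL2L11, which also promotes apoptosis, rose by 0.82 (adjusted p = 0.0417), but its shift in clone c was -0.04. None of these lists passed as a whole (camera adjusted p = 0.442 to 0.996, apoptosis regulators included). The calls of BCL2L11, SESN1, CCNB2 and FEN1 each ended without any 1 of the V5 vectors, and without other single arrays (adjusted p up to 0.149).

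Matrix and mesenchymal genes did not shift together. FN1, fibronectin, rose by 1.02 (SE 0.13, adjusted p = 0.000913) with all 4 of its probe sets called. ACTA2, smooth muscle actin, fell by 1.46 (SE 0.18, adjusted p = 0.000913). They were the 2 calls among 14 mesenchymal genes (4 adjusted over the list alone; camera adjusted p = 0.925). Of 24 matrix genes the laminin chain LAMA4 rose by 0.68, LAMC1 fell by 0.48, the collagen COL18A1 fell by 0.80 (fell by 0.42 with the mean of its probe sets, adjusted p = 0.0909) and 21 did not pass (3 adjusted over the list alone; camera adjusted p = 0.341). The tight junction gene CLDN1 fell by 0.67 (adjusted p = 0.0160), the only call among 13 epithelial genes (2 adjusted over the list alone; camera adjusted p = 0.925). Markers of other cell types did not pass as groups. LOX, a collagen crosslinking enzyme of fibroblasts, rose by 0.70 as 1 of 4 measured fibroblast markers (camera adjusted p = 0.996), and 0 of 3 squamous markers were called (camera adjusted p = 0.851). Of white blood cell markers and of liver and gut markers 0 passed the filter, and of lung markers 1 did.

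The HOXD13 lines did not respond evenly, and a sign of RNA integrity differed between them. The shifts of the mix and clones a and b correlated across genes at r = 0.855 to 0.962, where genes are not independent replicates. Those of clone c correlated with the mix, clone a and clone b at 0.162, -0.0983 and -0.204. In 2994 genes (28.9%) all 4 lines lay on 1 side of the vectors, against 8.08% in simulated data without change, with the real spread of each group and independent lines, which these are not. The ACTB 3 prime to 5 prime difference lay 0.57 above the V5 vector mean in clone c, and stood at -0.10, -0.23 and -0.41 from it in the mix, clone a and clone b. The RAS-MAPK, NOTCH and histone medians rank these 4 lines in the reverse order. The GAPDH difference was 0.86 in clone c against 0.53, 0.57 and 0.56 in the mix and clones a and b, and 0.68 to 0.72 in the V5 vectors. The Spearman correlation across genes of shift with genomic length was 0.266 in clone c against -0.152, -0.209 and -0.246 in the mix and clones a and b, and -0.0593 to 0.0905 in the V5 vectors.

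The count of HOXD13 calls was 303 to 582 without any 1 of the V5 vector arrays, the mix, clone a or clone b. It was 3701 without clone c (1959 rises, 1742 falls) and 1797 without HOXD9 clone c. It was 2596 with the ACTB difference as a covariate and 3259 without the 3 arrays of deviating ACTB difference. Simulated data with 200 changed genes and independent genes and lines gave 13.8% false calls. The share among the real calls is not known. Of the 57 genes named by the rule 34 lost their call without at least 1 of the V5 vectors, the mix, clone a or clone b (adjusted p up to 0.152), among them FOS, MYC, C1RL, MSX2, BMP2, HOXD10, JAG1, HEY1, BAMBI, HBEGF, H2AC6, H2BC5 and UQCRC1, 12 of the 34 also lost it without an array of the HA set, and without clone c 4 of the 8 lists passed (RAS-MAPK output, NOTCH targets, TGF-beta and BMP targets, histone genes), the others having adjusted p of 0.0590 to 0.0729.

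The effects of the factors differed in 997 genes when the difference itself was tested, 840 with a higher and 157 with a lower HOXD9 than HOXD13 effect, 287 of them at least 2-fold. OR51E2 had a difference of -4.51 (SE 0.19, adjusted p = 4.38e-08), but lay at the floor in the HA vectors and the HOXD9 lines (2.23 in both), where an effect of HOXD9 cannot be measured. AMBN (-2.86), PTGER4 (-2.78, adjusted p = 0.000119), TOX3 (-2.71) and RFX6 (-2.27) followed. AMBN, TOX3 and RFX6 were also near the floor in the HOXD9 lines, at 2.58, 3.36 and 2.81, so the sizes of their differences depend on the background model. In the other direction KLHDC7B differed by 2.46 (SE 0.17, adjusted p = 1.46e-05), with a HOXD9 log2 fold change of 0.56. UNC5B-AS1 (2.41), GSTZ1 (2.35), DNAH17 (2.35) and ATP6V0E2-AS1 (2.28, adjusted p = 0.0400) followed, the last losing its call without any 1 array other than HOXD9 clone b or HOXD13 clone c (adjusted p = 0.0620 to 0.0935). RAC3 also differed (1.29, adjusted p = 0.00139).

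**Figure D4:**
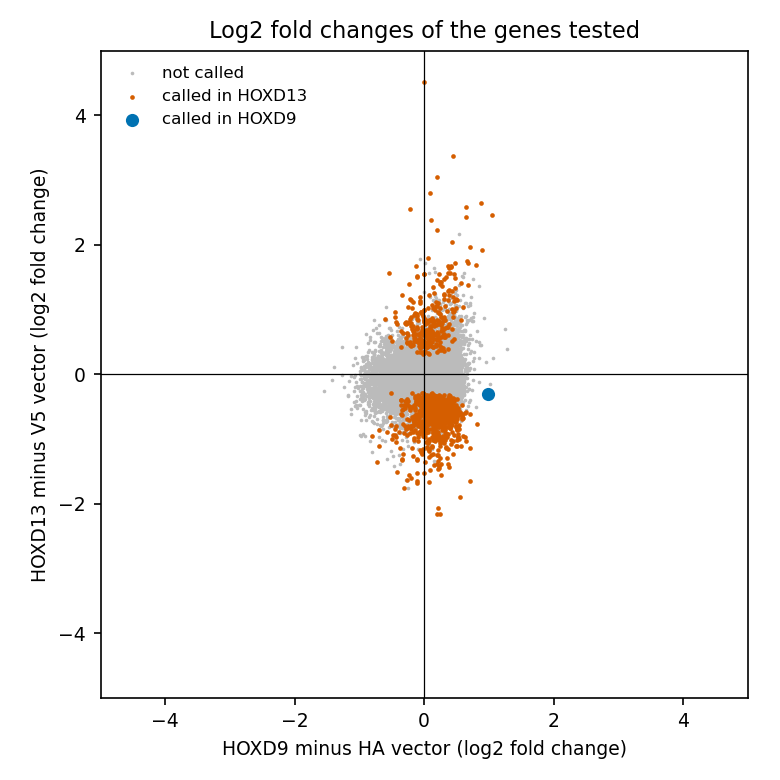
Each point is 1 of the 10349 genes tested, with its HOXD9 log2 fold change on the horizontal and its HOXD13 log2 fold change on the vertical axis, coloured by the comparison in which it was called. OR51E2 stands alone at 4.51 on the vertical axis and, at the floor in the HA set, 0 on the horizontal, and RAC3, the 1 gene called in HOXD9, lies at 0.99 on the horizontal.

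For FOS (-1.93, adjusted p = 0.174) and MYC (-1.24, adjusted p = 0.254) the difference between the factors did not pass, although both rose with HOXD13. FOS was near the floor in the HA set, at 3.05 in the vectors and 3.70 in the HOXD9 lines, so its HOXD9 effect is poorly measured. CDKN2B (-1.57, adjusted p = 0.00662), FN1 (-0.96, adjusted p = 0.00747), BAX (1.34, adjusted p = 0.00143) and ACTA2 (1.66, adjusted p = 0.00338) did differ. RAS-MAPK output genes were lower with HOXD9 than with HOXD13 as a list, with a median of -0.52 and 0 of 17 called (0 adjusted over the list alone). Their camera adjusted p was 0.0217 (adjusted p = 0.809 with an estimated correlation). Oxidative phosphorylation genes were higher, with a median of 0.32 and 4 of 25 called, NDUFB8, NDUFS3, NDUFV1 and UQCRC1 (5 adjusted over the list alone). Their camera adjusted p was 0.0217 (adjusted p = 0.602 with an estimated correlation). No gene was called in both comparisons by limma, against 0.0288 in the same direction for independent lists. At an unadjusted p under 0.05 there were 120 genes in the same and 510 in opposite directions, against 319 and 336 for independent lists. Without HOXD13 clone c they were 1318 and 572 (913 and 906 for independent lists), and 363 genes were called in the same and 150 in opposite directions (203 and 191). Across genes the log2 fold changes correlated at r = 0.128 (rho = 0.104). Shifts also went with gene length, with 1 sign in HOXD13 clone c and the other sign in the other HOX lines. Such a trend cannot be told apart here from effects shared by the factors.

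Each effect was measured within its own tag set, so tag, vector and normalization set differ along with the HOX gene. The count of calls of the difference was 384 to 438 without any 1 vector array, 603 without the HOXD13 mix and 649 without HOXD13 clone a. It was 1665 without HOXD9 clone b. Without HOXD13 clone c it was 2299, with 1415 higher and 884 lower, so the excess of higher HOXD9 effects shrank. It was 2025 with the ACTB difference as a covariate and 2058 without the 3 arrays of deviating ACTB difference. Shared calls became 363 without HOXD13 clone c and 4 without HOXD9 clone b. The 2 lists became 0 or 1 without HOXD9 clone a or b or HOXD13 clone a or b, and 7 without HOXD13 clone c.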

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

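The tests below address patterns seen in the results, so they were chosen after these were seen. Only for clone c against RNA integrity and RAS-MAPK output against gene length were the predictions written before the test was run.

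In 77 groups of 4 lines, 6 had an array farther from the rest than Dixon's critical value allows, 5 of them HOXD13 clone c. Chance alone does this in about 1 in 20 groups. In the HOXD13 lines the ratio of gap to range was 0.865 for MYC, 0.840 for FN1, 0.840 for BAMBI, 0.867 for the dimmest HOXD13 probe set and 0.893 for the GAPDH 3 prime to 5 prime difference, each with clone c as the far array. In the HOXD9 lines it was 0.842 for the GAPDH difference, with HOXD9 clone c as the far array. The ratio does not measure size. HOXD9 clone c lay at 0.607 in the GAPDH difference, against 0.639 to 0.645 in the other HOXD9 lines. For the dimmest HOXD13 probe set HOXD13 clone c lay at 8.26, against 8.39 to 8.41. Most groups were genes chosen from these same arrays.

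A test of the difference between the HOXD9 and HOXD13 effects called 997 genes. The largest positive differences were KLHDC7B (2.46), UNC5B-AS1 (2.41), GSTZ1 (2.35), DNAH17 (2.35) and ATP6V0E2-AS1 (2.28). The largest negative ones were OR51E2 (-4.51), AMBN (-2.86), PTGER4 (-2.78), TOX3 (-2.71) and RFX6 (-2.27), of which OR51E2 lay at the floor and AMBN, TOX3 and RFX6 near it in the HA set.

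More genes fell than rose among the HOXD13 calls, 803 against 298. A shift of the HOXD13 arrays as a whole cannot be told apart from changes of single genes: the median of all genes was -0.0313, but the 7 arrays of the set share 1 distribution, which holds that median near 0. Without clone c 47.1% of the calls were falls, against 80.2% to 81.5% without any other line, although both numbers rose without it, to 1742 falls and 1959 rises. It lay on the side of the other lines in 70.7% of these falls and 25.9% of these rises, so its values may have kept more rises than falls from being called. No biological explanation was tested, since the labels name no difference between the lines.

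HOXD13 clone c stood apart from the mix and from clones a and b. Its brightest HOXD13 probe set lay 5.23 above the highest V5 vector, which argues against a mislabelled vector, and RNA of another cell type is argued against by 0% of the markers of each of 5 cell types being raised in it. RNA integrity stays a candidate explanation: over the 8 HOX lines the ACTB difference and the leading component of the shifts (49.0% of the variance) had r = 0.723 (exact permutation p = 0.0505, adjusted 0.101) and rho = 0.643 (exact permutation p = 0.0962, adjusted 0.192). Without the 2 lines farthest out in the ACTB difference, HOXD13 clone c and HOXD9 clone a, r was 0.246, so the relation rests on them. The 4 lines per set are too few to test it within a set. The component sets HOXD13 clone c (score 52.3) against HOXD9 clones c (-54.4) and a (-27.0). It is therefore not a measure of the distance between HOXD13 clone c and the other HOXD13 lines alone. A biological difference of clone c, such as the site of integration, was not tested.

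RAS-MAPK output genes were called higher as a list in the HOXD13 lines at the preset correlation and not with an estimated one (adjusted p = 0.535), with 3 of 17 called and a median of -0.22 in clone c. Gene length was tested on the mean of the lines only. The list's median genomic length in GRCh38.p14 was 7.52 kb against 32.9 kb for all genes. Of 10000 random lists matched on length and level, 0% reached the list's median of 0.66 (highest 0.52). Genes of like length and level thus did not shift as far in that mean. Within a line the test cannot decide, since trends with length oppose and partly cancel in the mean. Spearman correlations of shift with length were -0.152, -0.209 and -0.246 in the mix and clones a and b, and 0.266 in clone c. The list medians rank these lines in the reverse order. Random lists also ignore correlation between genes, so gene length is not excluded. RNA integrity as the source of the shift cannot be told apart: with the ACTB difference as a covariate the median was 0.65, but the HOXD13 lines lay at -0.04 from the vectors in that difference on average, so the covariate could move little. For the inequality between lines RNA integrity cannot be told apart from line differences: over the 8 lines r was -0.496 (exact permutation p = 0.213, adjusted 0.213) and rho -0.429 (exact permutation p = 0.299, adjusted 0.299), with -0.858 without the 2 farthest lines, and the lines are few and not independent. An effect of HOXD13 on this pathway in the mix and clones a and b is a hypothesis. It may hold beside RNA integrity or gene length, and it was not tested apart from these arrays.

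Other splits of the same arrays into groups of the same sizes were fitted. Chance cannot be excluded for the count of HOXD9 calls (1, highest other 1570; 2 of 35 splits as large) or of HOXD13 calls (1101, highest other 3747; 2 of 35). Those highest splits set the mix and clones a and c of HOXD9 against clone b and the vectors, and the mix and clones a and b of HOXD13 against clone c and the vectors, which points to a structure of the samples in which 1 clone departs from the other lines of its HOX gene. Every remaining split of either set gave 0 calls. Each highest split is the real one with 1 clone moved to the vectors, so it still holds much of the HOX contrast. With 35 splits, 1 such split is enough to exceed 5%, so these splits cannot decide on chance for the 2 counts. For the difference of effects only the real split among 100 drawn from 1225 gave as many (997, highest other 460; 1 of 100), which would exclude chance if the arrays were exchangeable. The lines are not independent, and undrawn splits gave more, 4249 for the highest HOXD13 split and 2176 together with that of HOXD9, so chance is not firmly excluded. It cannot be excluded for the lists called in HOXD13 (8, highest other 9; 2 of 35) or in the difference (2, highest other 10; 40 of 100). For the lists called in HOXD9 (0, highest other 5; 35 of 35) and the genes called in both comparisons (0, highest other 0; 100 of 100) every split reaches the real value of 0, so these counts decide nothing about chance.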

How the results depend on the processing

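The ACTB covariate, the fit without the 3 arrays of deviating ACTB difference (HOXD9 clone a, HOXD13 clones b and c), gene by gene array weights, a spread for each group and the HOXD cluster list without the transfected gene were chosen after seeing the data. The counts 1 (HOXD9), 1101 (HOXD13) and 997 (difference) moved by less than 1.5 times with a filter at log2 7, quantile normalization of all arrays, centring and an intensity trend with a robust prior. Counts given next are in that order. Minimum 2-fold changes gave 0 (limma, 2429 at an unadjusted p under 0.05), 172 and 287, by construction. No filter gave 6 for HOXD9 and 1 shared call, the mean of a gene's probe sets gave 2 for HOXD9, and all probe sets gave 6 and 1721 over more tests. Fits on 2 groups gave 0 for HOXD9 (limma, 2423 at an unadjusted p under 0.05). A spread for each group gave 1772 for HOXD13. Array weights gave 7839, 8862 and 8371, with 4139 shared, in a fit where single arrays dominated (weight 765 for the HOXD9 mix, 246.5 for HOXD13 clone a, estimation not converged). Gene by gene weights gave 5043, 7522 and 6451, with 2450 shared. The ACTB covariate gave 50, 2596 and 2025, with 8 shared, and the fit without the 3 arrays 102, 3259 and 2058, with 42 shared. Apart from those stated, the cause was not tested.

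Leaving out each array gave 0 to 1100 for HOXD9 (0 without HA vector 1 or 3, 880 without HOXD9 clone b, 1100 without HOXD13 clone c through the shared spread), 303 to 3701 for HOXD13 (without V5 vector 3 and clone c; 1797 without HOXD9 clone c) and 384 to 2299 for the difference (without V5 vector 3 and HOXD13 clone c). Shared calls ran from 0 to 363, lists from 0 to 0 for HOXD9, 4 to 9 for HOXD13 and 0 to 7 for the difference. With an estimated correlation the lists called were 0 in HOXD13 and 0 in the difference (camera, 2 and 1 at an unadjusted p under 0.05). Without the transfected gene in the HOXD cluster list 7 lists passed in HOXD13. The transgene values ran from 0.14 to 0.21 and 4.01 to 4.38 (dimmer and brighter HOXD9 probe set), 5.44 to 5.56 and 4.92 to 5.12 (brightest and dimmest HOXD13 probe set) and 0.81 to 1.33 (middle HOXD13 probe set, called only with all arrays or without clone c of either HOX gene). MKI67 turned to -0.50 (adjusted p = 0.11) with the mean of its probe sets, which disagree. No other named gene changed direction. Of the results of named genes, 20 of 68 lost their call without the filter, 25 of 58 in fits on 2 groups and 5 of 68 with the mean of a gene's probe sets (HOXD10, BCL2L11, COL18A1, H2BC5 and SYT11, adjusted p = 0.0521 to 0.11). That mean also moved DNAH17 from -2.16 to -1.24 (2.35 to 1.46 in the difference), COL18A1 from -0.80 to -0.42 and HOXD13 from 0.98 to 3.84. Array weights moved CBX7 from -0.81 to -1.35.

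Same-numbered arrays showed no pairing: deviations of same-numbered HA and V5 vectors correlated at -0.0297, 0.00346 and -0.0301, and those of the mix and clones a, b and c of the HOX genes at -0.232, 0.0423, -0.619 and -0.576. With the replicate block the difference of effects had 197 calls and not 997, and 3 of its 10 named genes were not called. The HA vector was not compared with the V5 vector, with or without a block, and pooled vectors were not used as controls, since the sets were normalized separately. Probe sets near the floor limit what can be seen of dim transcripts.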

Other observations

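The tests on the clones and on shared directions below were chosen after the results were seen, and the gene lists were fixed before the data were examined.

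Several stress and biosynthesis genes fell singly in the HOXD13 lines, and none of the lists that follow passed as a group. Of all 10349 genes tested 1101 were called, 803 of them lower. The unfolded protein, interferon and mevalonate lists had a larger share of falls than that. Their calls are few, and without a pass by camera they do not make a result for the list. Of 21 genes of the unfolded protein and amino acid response 5 fell and 0 rose (5 adjusted over the list alone; camera adjusted p = 0.341). TRIB3, a pseudokinase induced by ATF4, fell by 0.66 (SE 0.10, adjusted p = 0.00202), DDIT3, the CHOP transcription factor, fell by 0.58 (adjusted p = 0.00887), the asparagine synthetase ASNS fell by 0.55 (adjusted p = 0.0272), PHGDH of serine synthesis fell by 0.50 (adjusted p = 0.00804) and the transcription factor XBP1 fell by 0.42 (adjusted p = 0.0303). Of 8 interferon-stimulated genes 3 fell (camera adjusted p = 0.925), among them the ubiquitin-like modifier ISG15, which fell by 0.96 (adjusted p = 0.0424), and the ubiquitin ligase HERC6, which fell by 1.0 (adjusted p = 0.0251). In the mevalonate pathway PMVK fell by 0.55 (adjusted p = 0.0134) and FDPS fell by 0.37 (adjusted p = 0.0404) while 11 of 13 genes did not pass. Among hypoxia and glycolysis genes the histone demethylase KDM3A rose by 0.48 (adjusted p = 0.0359), the glycolytic enzyme ENO1 fell by 0.32 (adjusted p = 0.0211) and 19 of 21 did not pass. The 23 ribosomal protein genes had a median of 0.00 (camera adjusted p = 0.888), and the 11 heat shock genes a median of -0.09 (camera adjusted p = 0.925). The adjusted p of the mevalonate list was 0.997, and that of the hypoxia list 0.442. Among 14 NRF2 genes 1 fell, ME1, the cytosolic malic enzyme, which fell by 0.49 (camera adjusted p = 0.925 for the list).

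The Polycomb subunits CBX7 and PHC2 fell by 0.81 (adjusted p = 0.0439) and fell by 0.51 (adjusted p = 0.0219), 2 of 16 measured Polycomb and Trithorax genes (camera adjusted p = 0.851). The neuronal genes MAP2, a microtubule protein, and SYT11, a synaptotagmin, fell by 1.11 (adjusted p = 0.0140) and fell by 0.67 (adjusted p = 0.00427), with 9 of 11 not passing (camera adjusted p = 0.925). PTGS2, which makes prostaglandins, rose by 1.12 (adjusted p = 0.0200) beside the receptor PTGER4, as 1 of 6 measured inflammatory genes (camera adjusted p = 0.0539). GAS1, a hedgehog coreceptor, rose by 0.85 as 1 of 7 measured hedgehog genes (camera adjusted p = 0.925). The calls of TRIB3 and SYT11 held without any 1 array. Those of DDIT3, ISG15, HERC6, PMVK, FDPS, KDM3A, ENO1, CBX7, PHC2 and MAP2 ended without V5 vector 3, and most of them without other single arrays (adjusted p = 0.0502 to 0.152).

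Genes at an unadjusted p under 0.05 in both comparisons moved more often in opposite directions (510, against 336 for independent lists) than in the same direction (120, against 319). This rests on HOXD13 clone c: without it 1318 moved in the same direction (against 913) and 572 in opposite directions (against 906). Across genes, the shifts of the 12 pairs of a HOXD9 line with the HOXD13 mix, clone a or clone b correlated at 0.107 to 0.395, and those of the 4 HOXD9 lines with HOXD13 clone c at -0.680 to -0.0416. The shifts of HOXD9 clone c and HOXD13 clone c had the r of -0.680, the lowest value among the 28 pairs of lines. Spearman correlations of shift with genomic length were -0.365 to -0.243 in the HOXD9 lines. They were -0.246 to -0.152 in the HOXD13 mix and clones a and b, and 0.266 in HOXD13 clone c. A trend with gene length or RNA integrity common to lines therefore cannot be told apart from effects shared by the HOX genes. The counts for independent lists do not allow for such a trend.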
